A study of Homo sapiens and Mus musculus with 78 samples.

How the data were processed

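KAS-seq measured single-stranded DNA in HEK293 cells, mESC and mouse liver. Per the labels, HEK293 cells were treated for 2 h with DMSO, 100 µM DRB or 1 µM triptolide and then labelled with N3-kethoxal. Sample titles name HEK293 and the growth protocol HEK293T. Of 78 samples in the series, 12 had a file used here: 10 peak lists (6 HEK293, 4 mouse) and 2 HEK293 RNA-seq tables. The other 66, which include inputs, low-cell-number libraries, 1,6-hexanediol time courses and ChIP-seq, were not analysed here.

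Per the submitters' processing notes, KAS reads went through Trim Galore, Bowtie2 2.3.3.1, SAMtools, bedtools and MACS2, on hg19 for human and mm10 for mouse. The deposited peak lists give a position, the -log10 p value, the fold enrichment ratio over the caller's background and the -log10 q value of each peak, as called by the authors in each library. The lists have no header, so the columns were told apart by their values. The control library and MACS2 settings are not given in the sources used here. The smallest -log10 q is about 2 in the HEK293 and mESC lists, and 1.36 and 1.38 in the liver lists, which hold 14.1% and 16.2% of peaks below 2. The lists give no read counts, so the depth of the KAS libraries is unknown and no intervals were computed. Per the submitters' processing notes, RNA reads were aligned with HISAT2 on hg19. The deposited RNA tables give raw fragment counts, FPM (fragments scaled to library size, not used for comparisons) and FPKM per RefSeq transcript; the tool is not given in the sources used here. The libraries held 48953164 and 35432178 fragments.

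Human genes were placed by the coordinates of 66631 RefSeq transcripts in the RNA tables. Of these, 1062 (1.59%) had no symbol and were left out. The longest transcript stood for each of 27436 genes, 605 of which had more than 1 locus, and the transcript with the highest FPKM at the locus gave the RNA level. Genes that overlap, or share reads with paralogs, are uncertain. Regions were the promoter (TSS ± 1 kb), the gene body (from 1 kb after the TSS to the end, genes of at least 3 kb), the 3 kb downstream, and the whole gene with 1 kb upstream. No mouse annotation was at hand, so mouse peaks are given by position. Profiles used genes of at least 1 FPKM with no other gene within 5 kb.

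The outcome was the share of a region covered by peaks, which cannot exceed 100% and does not measure signal height. Shares were arcsine square root transformed and compared with limma 3.58.1 (R 4.3.3), with Benjamini-Hochberg adjustment, in regions with a peak base in at least 2 of the 6 HEK293 libraries. The fit written before the data were examined used all 6 libraries and limma's usual prior. On simulated data with DMSO-like noise and a sparse group beside the compared ones it gave 12.6% to 34.5% false calls with 3000 changed regions, and 43.4% to 78.4% with 200. Among 14 settings tested on simulated data, the one used takes the 4 libraries of a comparison and a prior from regions with residual variance above 0.0001. It gave 1.01% to 5.26% and 0% to 10.3% false calls. A variance floor with all 6 libraries gave fewer, 0% to 1.03% and 0%. Where nothing was called, the rate counted as 0%. With 200 changed regions the floor called nothing except in bodies that lost all coverage (38.7% recovered). The setting used called nothing in 200 promoters or downstream regions lowered to 50% of their coverage. Nor did the floor with 3000 such promoters or downstream regions. Of 3000 promoters that lost all coverage, the setting used recovered 88.9% and the floor 56.7%. Of promoters lowered to 50% of their coverage, the setting used recovered 18.1% of 3000 and 0% of 200, and the floor 0% of either. The simulated changes were falls only, and neither of the compared groups was sparse. These rates therefore do not cover rises in coverage or comparisons with triptolide. The setting used departs from the design in both libraries and prior, and real counts under several settings had been seen before it was chosen. HEK293 comparisons share their DMSO libraries, so no overlap between their gene calls was tested; triptolide and DRB were compared directly.

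Comparisons, preset lists and alternatives were otherwise fixed before the data were examined, except those named below. Covered lengths were compared by log2 ratio, with a 2-sided exact permutation test. Preset lists were immediate-early, heat shock protein, ribosomal protein, replication-dependent histone, p53 target, glycolysis, nuclear long noncoding RNA, Pol II-transcribed snRNA, Pol III-transcribed RNA, transcription machinery and tissue-restricted genes. They were compared with camera (inter-gene correlation 0.01, 6-library fit as designed, lists of at least 5 tested members, adjusted over the lists). Of 1000 random lists per comparison and size, 0.5% to 4.5% had a camera p under 0.05. Replicate numbers were not treated as pairs. The correlation of replicate deviations was 0.0169 between DMSO and DRB, -0.0209 between DMSO and triptolide and 0.00494 between DRB and triptolide. Most genes had no peak in either triptolide library, so the last 2 values could hardly show pairing. The replicate block was run as an alternative.

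Genes named in the text followed a rule set beforehand. For DRB and for triptolide against DMSO these were the 8 largest body falls among called genes of at least 10 FPKM with both treated libraries below both DMSO libraries, ties by FPKM. The 6 largest rises in promoter and in body coverage followed, at any FPKM. Of each preset list up to 4 members with the highest FPKM were named, or for noncoding lists those with the largest treated coverage. For RNA, these were the 5 genes of highest FPKM without a DMSO peak and the 5 of at least 3 kb and under 0.1 FPKM with the largest DMSO body coverage. In mouse they were the 5 widest peaks per group present in both replicates, of which some are printed. Some genes that the rule names are not reported here.

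Alternatives covered the transformation, filters, the better-scored part of each list, isolated genes, promoter width, pseudocounts, fry, camera with an estimated correlation, a replicate block and each library left out. Chosen after seeing the data were the variance estimates, the transcript with the highest FPKM as gene model, cameraPR, the liver limit at -log10 q of 2, and the overlap measures. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.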

Results

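The assay, KAS-seq, maps single-stranded DNA in living cells: N3-kethoxal reacts with unpaired guanines, and the marked fragments are biotinylated, enriched and sequenced. In all, 10 libraries had peak lists. They came from the human embryonic kidney line HEK293 (2 libraries each of DMSO, DRB and triptolide), mouse embryonic stem cells (mESC, 2 libraries) and mouse liver (2 libraries). A further 2 HEK293 RNA-seq libraries had expression tables. Values after ± are standard deviations of the 2 libraries of a group, unless another number is given. The sequencing depth of the KAS libraries is unknown, since the lists hold no read counts. The RNA-seq libraries held 48953164 and 35432178 fragments. The labels do not say how separate the replicates were, so p-values measure at most the spread between these samples, which may be technical. Where replicates are equal in both groups, a region has no spread of its own. Its p then rests on the prior variance taken from other regions.

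In HEK293 the DMSO libraries had 45288 and 43182 peaks covering 123.548 and 122.487 Mb. The DRB libraries had 16222 and 16817 peaks covering 27.4032 and 28.7811 Mb, and the triptolide libraries 3625 and 3750 peaks covering 2.39113 and 2.5071 Mb. Replicates shared 77.4% ± 0.472 of their covered bases in DMSO, 80.4% ± 2.79 in DRB and 68.3% ± 2.29 in triptolide. Mean peak width was 2782 bp ± 76.7 in DMSO, 1700.4 bp ± 15.7 in DRB and 664 bp ± 6.32 in triptolide, and median width 1163 bp ± 33.9, 1112.5 bp ± 12.02 and 369.5 bp ± 0.707. In the mouse samples the lists covered 67.0662 and 57.8995 Mb in mESC and 15.0107 and 24.1003 Mb in liver.

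**Figure D1:**
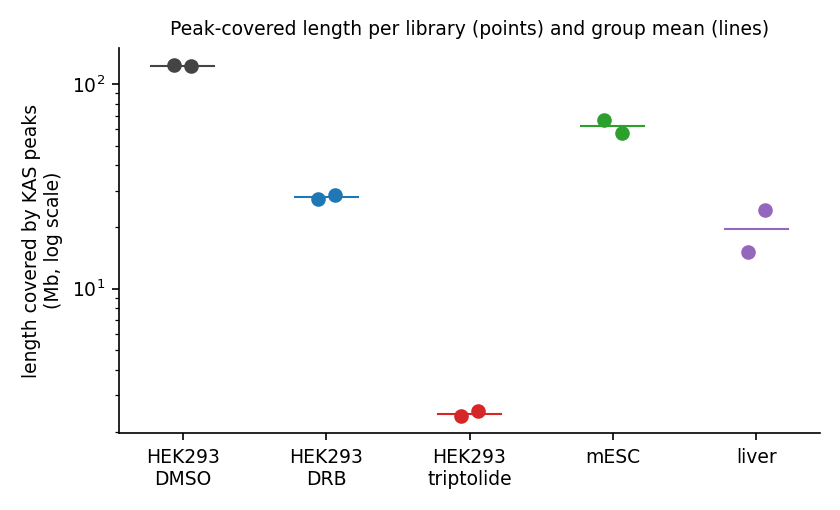
Length of genome covered by KAS peaks (Mb, log axis) in each library (points) with the group mean (line). The HEK293 groups lie at 123, 28.1 and 2.45 Mb for DMSO, DRB and triptolide, with replicates close together, while the liver libraries lie apart at 15.0107 and 24.1003 Mb.

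DRB inhibits CDK9, the kinase that releases paused RNA polymerase II into elongation, and the comparison with DMSO asks where peaks of single-stranded DNA were lost under it. Covered length fell by 2.13 on the log2 scale, 4.38-fold, and the log2 ratios of single libraries ran from -2.17 to -2.09. The 2-sided exact permutation test of 2 against 2 libraries cannot give a p below 0.333. Of the bases covered in both DMSO libraries in promoters (TSS ± 1 kb, 11.6 Mb), DRB libraries still covered 72.1% ± 0.900. Of those in gene bodies (57.6 Mb) they covered 9.83% ± 0.407. The difference was 62.2 ± 0.493 percentage points and had the same direction in both DRB libraries. Promoters held 25.3% ± 0.631 of the peaks in DMSO and 60.7% ± 0.735 in DRB. Body peaks went from 26047 ± 1175 to 3353 ± 245, downstream peaks from 2586.5 ± 40.3 to 558 ± 25.5, intergenic peaks from 4058.5 ± 153 to 2403.5 ± 7.78 and promoter peaks from 11044 ± 93.3 to 9735 ± 129.

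**Figure D2:**
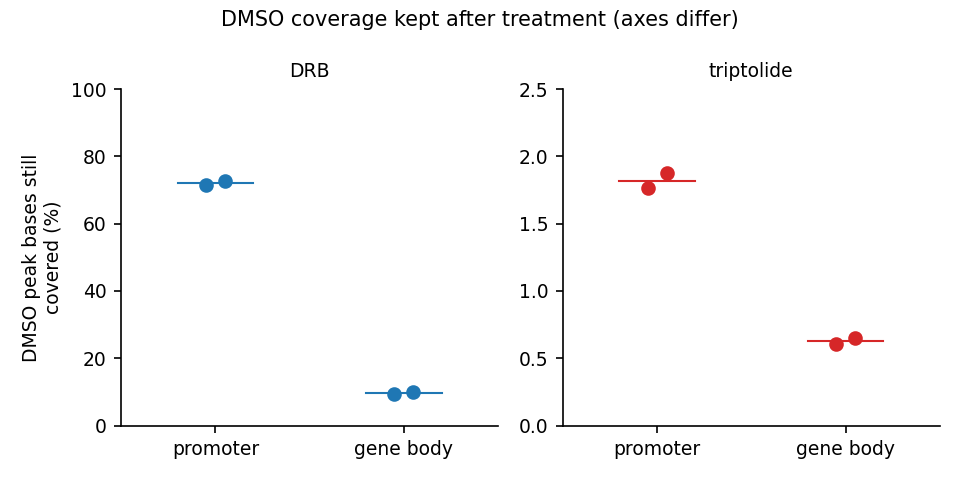
Share of the bases covered in both DMSO libraries (%) that each treated library (points) still covered in promoters and gene bodies, with means (lines). The vertical scales differ. DRB kept 72.1% in promoters and 9.83% in bodies, triptolide 1.82% and 0.626%.

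Along 1468 expressed genes of at least 50 kb with no other gene within 5 kb, coverage from 5 to 1 kb before the TSS was 5.75% ± 0.0204 in DMSO and 0.621% ± 0.0617 in DRB. In the last kb before the TSS it was 32.6% ± 0.396 and 28.5% ± 0.602. Coverage in the first kb after the TSS was 41.2% ± 0.551 in DMSO and 49.3% ± 1.63 in DRB. From 1 to 2 kb it was 11.7% ± 0.191 and 11.2% ± 0.705, a difference within the spread between replicates. From 2 to 5 kb it was 6.94% ± 0.120 in DMSO and 1.50% ± 0.172 in DRB, and from 5 to 10 kb 8.03% ± 0.268 and 0.365% ± 0.0528. At gene ends (2964 genes of at least 10 kb) DMSO coverage rose from 26.3% ± 0.171 in the last kb of the gene to 48.9% ± 0.104 at 1 to 2 kb beyond it, where DRB libraries had 3.52% ± 0.129.

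**Figure D3:**
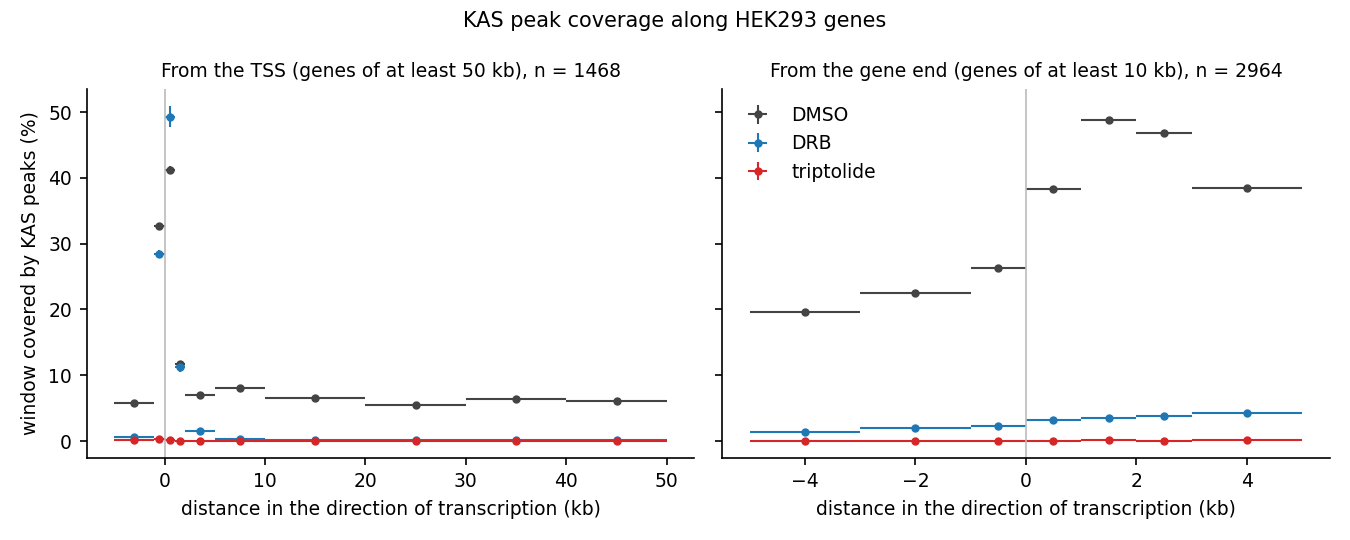
Share of each window covered by KAS peaks (%) by distance in kb from the TSS (left) and from the gene end (right), as group mean with SD; horizontal bars span the window. DRB lies above DMSO in the first kb after the TSS (49.3% and 41.2%) and below it from 2 kb on and upstream of the TSS, DMSO is highest at 48.9% at 1 to 2 kb past the gene end, and triptolide stays at 0.328% or below in every window.

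By gene, 4573 gene bodies had a peak in both DMSO and neither DRB library and 153 the reverse, among 10886 tested. The other 2 splits of these 4 libraries gave 58 and 62 such genes. Genes lost or gained in both treated libraries cannot count in such splits, so in each region they measure noise only in part. In the 3 kb beyond gene ends the counts were 7602 lost and 91 gained of 11300, against 26 and 20 for the other splits. At promoters they were 1676 lost and 315 gained of 13409, against 79 and 55, and 10537 promoters had a peak in all 4 libraries. With limma at an adjusted p threshold of 0.05, body coverage changed in 8378 genes (188 higher, 8190 lower) and downstream coverage in 9301 (168 higher, 9133 lower). The higher body calls were 92 or 89 without DRB replicate 1 or 2 and 104 or 100 without DMSO replicate 1 or 2. The higher downstream calls were 100 or 84 without DRB replicate 1 or 2.

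Promoter coverage changed in 3490 genes, 1043 higher and 2447 lower. This count depended on the fit. The fit as designed, with all 6 libraries and another prior, gave 5257 (2205 higher, 3052 lower), all 6 libraries alone 5004, the other prior alone 3565, and all 6 libraries with a variance floor 882 (60 higher, 822 lower). Without DRB replicate 1 it was 1911 (310 higher), and without DRB replicate 2 it was 1966 (292 higher). Among genes with no other gene within 5 kb, 423 of 975 calls were higher.

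The largest falls in body coverage among genes of at least 10 FPKM were from 100% in both DMSO libraries to 0% in both DRB libraries. The limma p is the same for each (adjusted p = 2.2e-05) and, with equal replicates, rests on the prior variance. Several genes tied at this fall, CCNG1 among them, and the 8 with the highest FPKM were RPS18 (chromosome 6, 33239852 to 33244281, hg19), EDF1, PNN (chromosome 14, 39644387 to 39652422), NME4, CA2, LOC100129148, SNRPE and POLR2J (chromosome 7, 102113548 to 102119381). Promoter coverage stayed at 84.1% ± 1.59 for PNN, from 93.5% ± 2.97, and at 69.0% ± 1.80 for POLR2J, from 74.3% ± 1.17. SNRPE kept 61.1% ± 8.49 of its promoter and RPS18 53.5% ± 5.02. The promoter of LOC100129148 went from 100% to 0%, and that of NME4 from 84.1% ± 22.5 to 7.48% ± 10.6.

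The largest rises with DRB were in promoters of TH2LCRR, FGFR4, RAB11FIP4 (chromosome 17, 29718642 to 29865236), USP50, TEKT2 (chromosome 1, 36549676 to 36553876) and SOWAHD (chromosome X, 118892576 to 118894165), which went from 0% in both DMSO to 100% in both DRB libraries (adjusted p = 0.00038 for each). RAB11FIP4, USP50 and SOWAHD are the ones of these with no other gene within 5 kb. Body coverage of TEKT2, TNNC2, LINC00942 and LOC102723544 went from 0% to 100%. That of TP53AIP1 reached 98.7% ± 1.88 from 0%, and that of ADAMTSL4 100% from 4.95% ± 7.01. In TH2LCRR the body moved the other way, from 59.2% ± 4.84 to 3.595% ± 2.21.

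Triptolide blocks initiation through the XPB subunit of TFIIH, and its comparison with DMSO asks which peaks remained under it. Covered length fell by 5.65 on the log2 scale, 50.2-fold, with log2 ratios of single libraries from -5.69 to -5.61, and no exact permutation p below 0.333 was possible. Of the bases covered in both DMSO libraries, 1.82% ± 0.0748 remained covered in promoters and 0.626% ± 0.0310 in bodies. The difference was 1.19 ± 0.0438 points. In long genes the first kb after the TSS fell to 0.196% ± 0.00212. Promoters lost their peak in both libraries at 11966 genes and gained one at 35, bodies at 9802 and 58, and downstream regions at 10763 and 29. The other splits of these 4 libraries gave at most 7 genes in each region. They pair a DMSO with a triptolide library, so with few triptolide peaks these counts were bound to be low. They are thus no measure of noise here. With limma, 12316 promoters changed (45 higher), 9595 bodies (54 higher) and 10781 downstream regions (28 higher). The higher calls were 27 in promoters without triptolide replicate 1, 24 in bodies without either triptolide replicate, and 11 or 14 downstream without triptolide replicate 1 or 2. Of all triptolide peaks, within DMSO peaks or not, 39.1% ± 0.978 were intergenic, against 9.28% ± 0.0406 in DMSO. The number of intergenic peaks went from 4058.5 ± 153 to 1352.5 ± 3.54.

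The largest falls among expressed genes were in bodies fully covered in DMSO and without a peak in triptolide (adjusted p = 2.8e-06 for each). Many genes tied at this fall, GAPDH, HSPA8, MYC and JUN among them, and the 8 with the highest FPKM were RPS6 (chromosome 9, 19376254 to 19380235), RPL26 (chromosome 17, 8280834 to 8286568), RPL5, the pseudogene RPL13AP5, RPL19, RPS4X, RACK1 and RPL35. Among the largest promoter rises were those in DMRTA2 (chromosome 1, 50883223 to 50889119) and LRCOL1 (chromosome 12, 133179736 to 133187037), both from 0% to 100%. MIR6745 rose from 8.35% ± 10.6 to 100%, TMEM181 from 0% to 90.9% ± 7.71 and CACNG1 from 0% to 79.7% ± 3.995. DMRTA2 and LRCOL1 promoters were also covered in DRB, at 86.4% ± 1.38 and 100%. The largest body rises were in LRCOL1 (66.5% ± 18.0), PACSIN3 (17.3% ± 2.43 to 79.1% ± 0.971), DMRTA2 (57.6% ± 2.74), SFTPA1 (43.6% ± 15.2), ASGR1 (43.3% ± 6.93) and LINC00304 (40.4% ± 19.7). Except in PACSIN3 these started from 0%. MIR6745 lies within PACSIN3.

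The direct comparison of triptolide with DRB asks which peaks present under DRB were absent under triptolide. Covered length was lower by 11.5-fold in triptolide (log2 ratio -3.52, single libraries -3.59 to -3.45). Of 11145 promoters with a peak in both DRB libraries, 10483 had none in either triptolide library, and 32 showed the reverse. For bodies 4492 of 5046 lost the peak and 57 showed the reverse, and downstream 2691 of 2952 and 30. With limma, 10968 promoters changed, 10930 of them lower in triptolide. Body calls numbered 2857 (2809 lower) but fell to 986 or 985 without triptolide replicate 1 or 2, and to 1731 or 1627 without DRB replicate 1 or 2. They were 813 on the untransformed share and 450 with all 6 libraries and a variance floor. Downstream calls numbered 2347 (2331 lower), 1476 or 1477 without triptolide replicate 1 or 2, and 614 with all 6 libraries and a variance floor.

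Preset gene lists were compared on whole-gene coverage. Falls were widespread with DRB: 8190 of 10886 tested bodies were lower, and the median whole-gene difference over 15310 tested genes was -10.0 points. The share of all genes called lower on whole-gene coverage is not given here. Counts of lower members thus do not by themselves show an effect particular to a list. With DRB, 16 of 18 tested glycolysis genes were lower by limma, also 16 adjusted over the list alone. GAPDH (chromosome 12, 6643571 to 6647541) kept 100% coverage, while ENO1 went from 98.5% ± 2.09 to 15.99% ± 0.0148 and LDHB from 95.4% ± 2.70 to 6.37% ± 0.141. ALDOA went from 100% to 87.8% ± 1.99, a call lost without DRB replicate 2. Of 24 p53 targets 14 were lower, 14 adjusted over the list alone. CCNG1 went from 95.3% ± 0.0753 to 15.1% ± 0.176, SESN2 from 97.8% ± 0.212 to 8.58% ± 0.353 and XPC from 46.2% ± 7.02 to 3.89% ± 0.199, and GADD45A was not called. Of 34 immediate-early genes 18 were lower and 1 higher, the same adjusted over the list alone. MYC (chromosome 8, 128747680 to 128755197) went from 100% to 38.6% ± 9.13 and ATF3 from 21.4% ± 2.86 to 3.39% ± 0.0827, while JUN at 93.5% ± 9.13 and JUND were not called.

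Of 30 heat shock protein genes 20 were lower and 1 higher, the same adjusted over the list alone. HSPA8 went from 100% to 49.9% ± 12.1, HSP90B1 from 80.1% ± 16.7 to 10.98% ± 0.0342, HSP90AB1 from 94.1% ± 8.41 to 43.4% ± 14.3 and HSP90AA1 from 28.5% ± 3.91 to 7.17% ± 0.197. The calls of ATF3 and HSP90AA1 were lost when any 1 of the 4 libraries was left out. Of 48 genes for the elongation and initiation machinery 31 were lower and 3 higher, with 33 and 3 adjusted over the list alone. POLR2J went from 92.5% ± 0.341 to 20.2% ± 0.528 and POLR2I from 76.2% ± 5.88 to 54.9% ± 6.65, the latter a call lost when any 1 of the 4 libraries was left out, and GTF2F2 and LARP7 were not called. Of 19 nuclear long noncoding RNA genes 14 were lower, 14 adjusted over the list alone, among them SNHG1 (100% to 75.9% ± 1.21) and SNHG7 (100% to 66.4% ± 19.9) but not SNHG3 or GAS5. Of 14 tested tissue-restricted genes 7 were lower and 3 higher, the same adjusted over the list alone. KRT10 and GAD1 were not called, and COL1A1 was not tested.

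Of 76 ribosomal protein genes 34 were lower, 34 adjusted over the list alone. RPS15, RPS6 and RPL26 were covered at 100%, 100% and 97.0% ± 0.199, and RPL5 went from 93.6% ± 0.601 to 69.9% ± 8.88, a call lost without DRB replicate 2 or either DMSO replicate. Of 52 histone genes 9 were lower, 6 adjusted over the list alone. H2AC25 stayed at 100% and H1-2 at 58.9% ± 2.49, from 60.1% ± 0.898, and H2BC12 was not called (84.7% ± 21.7 to 32.4% ± 9.57, adjusted p = 0.054). H2BC5 was called lower, 31.9% ± 1.16 to 19.2% ± 1.40, a call lost when any 1 of the 4 libraries was left out, and it did not change with the transcript of highest FPKM as gene model (adjusted p = 1). Of 8 Pol II-transcribed snRNA genes 4 were lower, 4 adjusted over the list alone. RNU11 went from 100% to 72.4% ± 6.17, while SNORA73B, RNU12 and RNVU1-19 were not called. SNORA73B, on the list under an older name, is a snoRNA gene within SNHG3, so its coverage is not separate from its host's. Of 9 Pol III-transcribed genes 1 was lower, 0 adjusted over the list alone. VTRNA1-1 stayed at 100%, and RMRP, RNU6ATAC and RPPH1 were not called.

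In limma's camera test, which sets a list against all other genes, 3 lists were less reduced with DRB than other genes. These were histone (adjusted p = 0.0017), Pol III-transcribed (adjusted p = 0.015) and ribosomal protein genes (adjusted p = 0.048). None of the 3 calls held with an estimated correlation (adjusted p = 0.21, 0.30 and 0.40). That correlation was -0.00790 for histone genes, below the preset 0.01, so the loss of their call does not come from correlated members. For the Pol III and ribosomal lists it was 0.0388 and 0.0346. Camera with an estimated correlation also tests on the few residual degrees of freedom of the fit. That makes its p larger at the same correlation. Here and below, a call lost under this alternative is thus not shown to be lost through correlated members. The median difference per gene was 0 points in the histone and Pol III lists and -5.18 points in the ribosomal list, where camera's upward direction and the median differ in sign. The ribosomal call was lost without DRB replicate 1 (adjusted p = 0.71) or 2 (adjusted p = 0.96) and the Pol III call without DRB replicate 1 (adjusted p = 0.13). With cameraPR on the fit of the gene calls both were lost (adjusted p = 0.12 for each), and with the replicate block the ribosomal call was lost (adjusted p = 0.058). The remaining 8 lists were not called. The whole-gene region of a gene under 1 kb lies within its promoter window. There DRB kept 72.1% of the bases covered in both DMSO libraries, against 9.83% in gene bodies. VTRNA1-1 (0.098 kb) and H2AC25 (0.496 kb) are such genes, while H2BC12 (8.566 kb) and H2BC5 (13.228 kb) are not. Gene length was not separated from list membership, so these calls do not show an effect particular to the lists.

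With triptolide nearly all list members lost coverage. Lower by limma were 18 of 18 glycolysis, 27 of 30 heat shock protein, 34 of 34 immediate-early, 19 of 19 long noncoding RNA, 23 of 24 p53 target, 8 of 8 snRNA, 52 of 52 histone, 76 of 76 ribosomal protein and 12 of 14 tissue-restricted genes, with the same counts adjusted over the list alone. The machinery list had 45 of 48, and 46 adjusted over the list alone. Pol III-transcribed genes had 6 of 9, 6 adjusted over the list alone. RNU6-2, present at 11 loci, stayed at 47.5% ± 1.21 from 49.4% ± 0.639, and VTRNA1-2 at 45.9% ± 0.195 from 40.9% ± 0.195. RNU6ATAC went from 87.7% ± 0.503 to 47.3% ± 1.13, and RPPH1 from 63.7% ± 3.11 to 49.4% ± 1.53, a call lost when any 1 of the 4 libraries was left out. RNU12 kept 40.9% ± 15.6 of 100%, POLR2J 7.89% ± 2.36 of 92.5% ± 0.341 and JPX 3.95% ± 0.538 of 47.8% ± 0.397. The calls of FTX, GTF2F2 and GAD1 were lost when any 1 of the 4 libraries was left out, that of LARP7 without either triptolide replicate, and that of KRT10 without either triptolide replicate or DMSO replicate 1. FTX kept 0.268% ± 0.0411 of 6.70% ± 2.05. Coverage fell to 0% in both libraries in MYC, JUN, HSPA8, GAPDH, RPS15, H2AC25, RNU11 and SNORA73B, each fully covered in DMSO.

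Median coverage with triptolide was 0% in every list but the Pol III list, so the size of a fall follows the coverage before it and camera cannot show a greater effect of triptolide on a list. Its calls for histone (adjusted p = 5.7e-07) and ribosomal protein genes (adjusted p = 1.0e-05) go with medians of 94.2% and 96.4% in DMSO. Neither held with an estimated correlation (adjusted p = 0.075 and 0.18), though for histone genes that correlation was again below the preset one. Pol III-transcribed genes fell by a median of 14.3 points (camera upward, adjusted p = 0.0014), a call lost with an estimated correlation (adjusted p = 0.18). It was also lost with cameraPR on the fit of the gene calls (adjusted p = 0.38), which in addition called glycolysis (adjusted p = 0.015) and long noncoding RNA genes (adjusted p = 4.7e-05). The ribosomal call was lost without DMSO replicate 1 or 2 (adjusted p = 0.55 and 0.56). Between triptolide and DRB, histone and ribosomal protein genes (adjusted p = 6.0e-13 for each), snRNA genes (adjusted p = 0.020) and machinery genes (adjusted p = 0.014) were called lower in triptolide, with the same limit. With an estimated correlation the histone call held (adjusted p = 0.029), and the ribosomal, snRNA and machinery calls were lost (adjusted p = 0.076, 0.22 and 0.14). CameraPR on the fit of the gene calls in addition called 4 lists lower. These were glycolysis (adjusted p = 0.016), heat shock protein (adjusted p = 0.024), immediate-early (adjusted p = 0.012) and long noncoding RNA genes (adjusted p = 0.0031). The machinery call was lost without DRB replicate 1 (adjusted p = 0.055) and with cameraPR (adjusted p = 0.28).

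Coverage in DMSO was set against RNA level to see how far open DNA and stable RNA go together. Across genes, which are not independent replicates, Spearman's correlation between FPKM and body coverage was 0.716 (21775 genes; 0.694 to 0.697 for pairs of single libraries) and that with promoter coverage 0.698 (27436 genes; 0.680 to 0.683). Among genes of at least 0.1 FPKM they were 0.534 and 0.418, so unexpressed genes carry part of both. A body peak was present in 8.34% ± 0.170 of genes below 0.1 FPKM, 72.1% ± 0.175 at 1 to 10 FPKM and 96.8% ± 0.525 at 100 FPKM or more. With DRB the last class kept a body peak in 77.6% ± 1.57 of genes, and mean body coverage in it went from 74.6% ± 0.0439 to 21.7% ± 0.881. With triptolide the share was 1.48% ± 0.262.

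**Figure D4:**
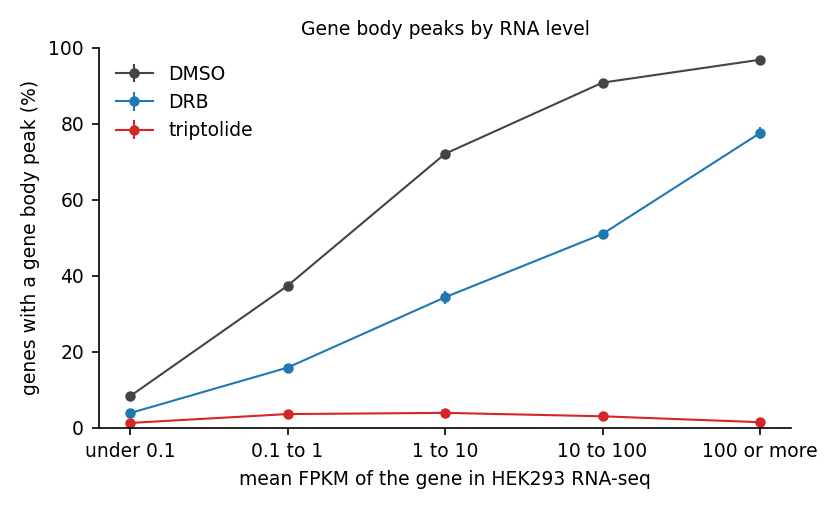
Share of genes with a KAS peak in the gene body (%) by RNA level (mean FPKM in 5 classes), as group mean with SD. The share rises with FPKM to 96.8% in DMSO and 77.6% in DRB and stays between 1.29% and 3.93% in triptolide.

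The protein-coding gene with the highest FPKM among the 5 named for having no DMSO peak in promoter or body was PPDPF (126 ± 4.85 FPKM; chromosome 20, 62152094 to 62153524). The other 4 were the microRNA genes MIR6891, MIR6866, MIR4444-2 and MIR4444-1, of under 0.1 kb, the last 2 placed at the same locus. All 5 are shorter than the 3 kb needed for a body region, so only their promoters were examined. Below 0.1 FPKM, the bodies of AATBC, C22orf31, CEND1, CIMAP1A and CTSW were covered at 100% in both DMSO libraries. Ties were broken by alphabetical order, so other genes may share this value. Overlap of these bodies with neighbouring genes was not examined. The RNA-seq libraries correlated across genes at r = 0.995 (log2 of FPKM + 0.1) and a Spearman correlation of 0.975. RPS15 had 4800.4 ± 2.66 FPKM and RPS6 3823 ± 51.6.

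In mouse, mESC were set beside liver, a dividing pluripotent culture beside an adult tissue. Covered length in mESC was 3.195-fold that in liver (log2 ratio 1.68, single libraries 1.26 to 2.16), with an exact permutation p no lower than 0.333. Liver bases lay in mESC peaks for 47.2% (41.3% to 53.1%), and mESC bases in liver peaks for 14.5% (11.9% to 17.2%). Within groups, 75.6% ± 7.85 of bases were shared in mESC and 67.2% ± 22.1 in liver. The widest mESC peak present in both replicates covered 124 kb of chromosome 4 (130663223 to 130787299, mm10), of which the liver libraries covered 3.70% and 4.71%. Peaks on chromosome 10 (62798158 to 62900495) and chromosome 14 (21512490 to 21593768) had no liver coverage. The widest liver peak covered 109 kb of chromosome 1 (67122732 to 67232207) and had no mESC coverage. A liver peak on chromosome 2 (31469173 to 31522143) was covered in mESC at 88.4% and 66.9%. Cells in culture and tissue were labelled by different protocols, so tissue and protocol cannot be separated. With liver peaks of -log10 q of at least 2 alone, liver covered 17.6 Mb ± 5.66 and the log2 ratio was 1.83. Genes under mouse peaks were not analysed here.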

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

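Peaks on hg19 sequences outside the assembled chromosomes entered no gene comparison, and some covered more bases in a treated group than in either DMSO library. The search was planned, but its inclusion of sequences at 0 in DMSO was set after the values were seen, and no explanation was tested. On chrUn_gl000220, which bears ribosomal DNA, the DRB libraries covered 54731 and 36795 bp (mean 45763), against 29744 and 29229 bp in DMSO. DRB also covered a mean of 2797.5 bp of chrUn_gl000228 (DMSO 592) and 2455 bp of chrUn_gl000224 (DMSO 796.5). With no DMSO coverage, DRB covered 1409.5 bp of chrUn_gl000214, 514.5 bp of chrUn_gl000212 and 467 bp of chrUn_gl000222. Triptolide, also from no DMSO coverage, covered 6668.5 bp of chrUn_gl000225, 2897.5 bp of chr9_gl000199_random, 2278.5 bp of chrUn_gl000216 and 586 bp of chrUn_gl000214. DRB replicate 1 also covered 7396, 1675 and 1815 bp of the first 3 of these, and DRB replicate 2 covered 0 bp of each. Such sequences hold repeats, where reads are placed uncertainly.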

How the results depend on the processing

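The variance estimates, the gene model by highest FPKM, cameraPR, the liver limit and the overlap measures are tests chosen after the results were seen. For the results that answer a comparison, 145 settings left the value within 1.5 times (counts) or 1 SD, and 74 moved it. Among isolated genes fewer were tested by construction; for the other settings the cause was not tested. Promoter calls for DRB against DMSO (3490) numbered 5257 with the fit as designed, 882 with all 6 libraries and a variance floor (as for each floor value here), 1539 with a peak in at least 4 libraries and 975 in isolated genes, and 1911 to 3089 with 1 library left out. Isolated genes gave 4806 promoter calls for triptolide against DMSO (11251 to 11433 with 1 library left out) and 4557 against DRB (10022 to 10733). Body calls with at least 4 libraries and in isolated genes were 3350 and 2017 for DRB (6095 to 6483 with 1 library left out) and 4432 and 2289 for triptolide (7087 to 8489). Triptolide against DRB body calls (2857) were 450 with the floor, 813 untransformed, 1469 with the better-scored part and 689 in isolated genes, and 985 (without triptolide replicate 2) to 1731 (without DRB replicate 1). Downstream calls were 1226 and 3205 for DRB and 2719 and 3367 for triptolide with at least 4 libraries and in isolated genes. Between triptolide and DRB (2347) they were 614 with the floor, 1206 with the better-scored part and 262 in isolated genes, and 1476 (without triptolide replicate 1) to 2391. The promoter minus body difference for DRB was 67.8 points with narrower promoters, 51.1 with TSS ± 2 kb and 74.96 in isolated genes, and 60.0 to 62.6 with 1 library left out; for triptolide it was 1.12 with ± 2 kb and 1.44 in isolated genes. The Spearman correlation between RNA and body coverage was 0.534 at 0.1 FPKM or more and 0.721 in isolated genes, Pearson's r was 0.554 and 0.574 with 0.1 and 1 added, and leaving out 1 library gave 0.696 to 0.716. For promoters the values were 0.418, 0.740, 0.643 and 0.603, and 0.683 to 0.696. The log2 ratio of covered length was -2.69 (DRB), -5.74 (triptolide) and -3.05 (triptolide against DRB) with the better-scored part, and by number of peaks -1.42, -3.58, -2.16 and, for mESC against liver, 0.98. On autosomes and X it was -5.74 and -3.60 for triptolide against DMSO and DRB. Replicates met by at least 1 base were 74.2% (DMSO), 84.5% (DRB) and 63.2% (triptolide), and those covered for most of their length 61.1% (DMSO), 50.5% (triptolide) and 66.9% (mESC). Lists called numbered 0 with estimated correlation, 1 with cameraPR for DRB, and 0 with estimated correlation for triptolide. With fry, which asks whether a list changed and not whether it differs from other genes, 10 and 11 lists were called, all downward. Camera with 1 library left out called 1 (without DRB replicate 1) to 3 for DRB and 2 to 5 (without either triptolide replicate). With the replicate block, body calls for triptolide against DRB were 1975 and promoter calls for DRB 3542, and list calls 2 and 3. With the transcript of highest FPKM, H2BC5, the 1 called with DRB among the 4 named histone genes, had an estimate of 0 and was not called, leaving 0 of these 4. Of all named DRB calls, 2 of 38 were lost with this gene model. Of 39 named DRB calls, 2 were lost with the replicate block, 2 with the other prior and 4 with the floor. Of 61 named triptolide calls, 3 were lost with the replicate block, 5 with the floor and 6 untransformed. Gene and list comparisons in mouse were not run for want of an annotation. With 1 library in an arm, it is assumed to vary like the other group. KAS depth is unknown, so weak regions cannot be told from uncovered ones.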

Other observations

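The tests on liver peaks and on wider DRB promoter peaks were set before their results were seen, though the -log10 q limit of 2 was chosen after the lists had been examined; those on triptolide peaks, neighbouring genes and long genes were chosen after.

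Triptolide libraries had 1730 and 1806 peaks outside DMSO peaks, and 51.2% (49.7% and 52.8%) of 1 library's were met in the other. Calls near the limit that do not repeat thus stay open only for the unmatched peaks. Of 913 repeated peaks, 32.5% were met by a DRB peak, against at most 2.41% for shifted positions. Weak signal that any loss of gene signal brings above the calling limit may contribute, but the remainder keeps this open. A biological response to triptolide also stays open and was not tested.

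The liver lists differ, with 59.1% of replicate 2 peaks met in replicate 1. The 9863 unmatched peaks had a median percentile by -log10 q of 24.3, against 70.3 for matched ones. This was the outcome predicted if 1 list reaches weaker peaks. It does not decide the point, since unmatched peaks can be the weaker ones in any pair of lists. No other pair was compared in this way. With only peaks of -log10 q of at least 2, 62.8% were met, so the looser limit of the liver lists does not account for the low overlap. That limit was nearly the same in both lists (smallest -log10 q 1.36 and 1.38), so it could not explain a difference between them. A difference between the liver samples was not tested.

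Higher promoter coverage after DRB could reflect wider peaks at promoters that already had one. Of the 1043 genes, 73.2% had a promoter peak in both DMSO libraries, which leaves the rest open. Among all 13409 tested promoters 12626 had one, a larger share. The 73.2% therefore does not show that higher calls favour promoters that already had a peak. Among isolated genes, fitted alone, 423 of 975 calls (43.4%) were higher, so overlap with neighbouring genes does not explain all higher calls. How many it explains stays open. The share rose because lower calls fell from 2447 to 552 while higher calls fell from 1043 to 423. The median fold enrichment of all peaks was 6.08 and 5.8 in the DRB libraries and 3.35 and 3.32 in DMSO. Whether loss of gene signal brings promoter signal above the calling limit, as raised for triptolide peaks, was not tested. Higher coverage by peaks called in each library thus does not show more single-stranded DNA. A biological effect of DRB at promoters stays open, as the count depends on the fit (882 to 5257 calls).

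In the 96 longest genes compared, DRB coverage as a share of DMSO coverage in the last 50 kb was 23.6 times (10.5 and 36.7 in the 2 libraries) that at 20 to 50 kb, where DRB covered 1 and 3 genes. The last 50 kb were covered at 1.39% and 1.48% in DRB and 1.22% and 1.26% in DMSO. Single genes went both ways, and 3 are given that were chosen after their values were seen. KLHL29 had 25.6 and 26.0 kb of coverage there in DRB and 10.6 and 10.3 kb in DMSO. CUX1 had 15.1 and 12.5 kb in DRB and 2.78 and 4.33 kb in DMSO, while STAG1 had 0.521 and 0.804 kb in DRB and 7.46 and 4.21 kb in DMSO. The ratio compares totals over genes and does not show coverage kept gene by gene.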
